A study of Drosophila melanogaster with 6 samples.

How the data were processed

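RNA was isolated from GFP-positive progenitor cells sorted from dissected and elastase-dissociated Drosophila melanogaster midguts, and libraries were made with a stranded kit that selects mRNA, per the labels. Flies carried a temperature-sensitive esg driver with a GFP reporter. The sample descriptions give 4 days of induction at 29 °C, while the growth protocol, worded for a different transgene, gives 1 day at 29 °C for flies 3 days old kept at 18 °C before. Which applies to these RNA libraries is not settled by the sources used here. The series has 3 control and 3 H1 RNAi libraries, and their groups and replicate letters come from the sample titles.

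The deposited values are TPM (transcript abundance scaled by gene length and library total) per gene and library, computed by the authors and rounded to 2 decimals, 1 column per library. The table holds 17807 genes, of which 4094 were listed at 0 in all 6 libraries. TPM divides by gene length and by the library total, so a large change in abundant genes shifts all others, and depth, and with it counting error, cannot be recovered. The submitters' processing notes name bcl2fastq and the dm6 genome build. The aligner, the counting tool, its treatment of strand and of multi-copy genes and the annotation are not given in the sources used here. Symbols were taken from a table of gene names that paired 17710 of the 17807 identifiers, and the 97 others took 0.384% to 0.454% of the TPM of a library. Coordinates are those of Ensembl release 115 on BDGP6.54, 1-based. Of the names on the lists, 59 matched no row, most of them transposable elements.

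The comparison of H1 RNAi with control used limma 3.58.1 in R 4.3.3. Genes with at least 1 TPM in at least 3 of the 6 libraries (8124 genes) were fitted on log2(TPM + 1), with a mean trend and robust variance moderation, and p-values were adjusted by the method of Benjamini and Hochberg at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes near or below 1 TPM. Errors of group means are SD over 3 libraries and errors of fold changes are limma's SE. An exact permutation test of 3 against 3 cannot give a p under 0.1, so none was used for single values. Tests of gene sets used camera with a preset correlation of 0.01 for lists with at least 5 tested members, with camera's estimated correlation and fry beside it. Calculations outside R used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

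The tests, 31 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered linker histone H1, core histones and variants, ISC and EB progenitor genes, Notch target genes, enterocyte digestive enzymes, enterocyte identity and junction genes, enteroendocrine hormones, enteroendocrine fate regulators, neuronal genes, germline genes, Hox and segmentation genes, the Polycomb group, heterochromatin factors, cell cycle genes, DNA damage and apoptosis genes, JNK and stress response genes, heat shock genes, JAK/STAT genes, EGFR and Wnt genes, antimicrobial and immune genes, and markers of visceral muscle, hemocytes, trachea, fat body and ovary. They also covered sex-linked indicator genes, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, detoxification genes and transposable elements. Named genes were the target rows, the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and no overlap between the groups, up to 4 members of each list with the smallest adjusted p, and 10 genes chosen by name, of which esg and Dl had no matching row. A named gene of the DNA damage and apoptosis list is not reported here.

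Alternatives were a pseudocount of 0.1 or 5, no filter on low values, a filter at 5 TPM, scaling by the trimmed mean of M values (TMM, trims of 0.3 and 0.05), quantile normalization, ordinary moderation without trend, array weights, the replicate letter as a block and leaving out each library in turn with the genes tested kept the same. The procedure was tested on simulated data with the control means and limma's moderated spreads of the 8124 genes and 200 genes changed by known folds, in 20 runs. It recovered 84.9% of 2-fold and 97% of 4-fold changes among genes above 5 TPM, 5.1% of its calls were false, and it called at most 1 gene per run when nothing changed (median 0). A simulated set of 20 genes shifted by -0.7 on the log2 scale was called in 100% of runs, and 2 of 400 unshifted sets were called. The simulated genes varied independently of each other, while the estimated correlation within real lists reached 0.77 (oxidative phosphorylation). No simulated library was set apart, as control B is in the real data. These rates of recovery and of false calls therefore do not carry over to the real data, where other splits of the libraries gave 2 to 13 lists.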

Results

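RNA was sequenced from progenitor cells of the adult fly midgut, the intestinal stem cells (ISC) and their enteroblast daughters (EB), sorted by a GFP reporter driven in esg-expressing cells. The libraries fall into 2 groups of 3, a control and a knockdown of the linker histone H1 by RNA interference (RNAi), with replicates lettered A, B and C. The question was how gene expression in these progenitors differs when H1, the histone that binds DNA between nucleosomes, is targeted. The labels give 70 guts per replicate and at most 100000 sorted cells, and do not say whether replicates came from separate crosses or days, so p-values measure the spread between these samples, which may be partly technical. Values were deposited as TPM, transcript abundance scaled by gene length and library total, so the sequencing depth is unknown. Between 7767 and 8316 genes per library reached 1 TPM. Mitochondrial transcripts took 3.36% to 4.30% of the TPM of a library and the 10 highest genes 10.1% to 11.2%.

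**Figure D1:**
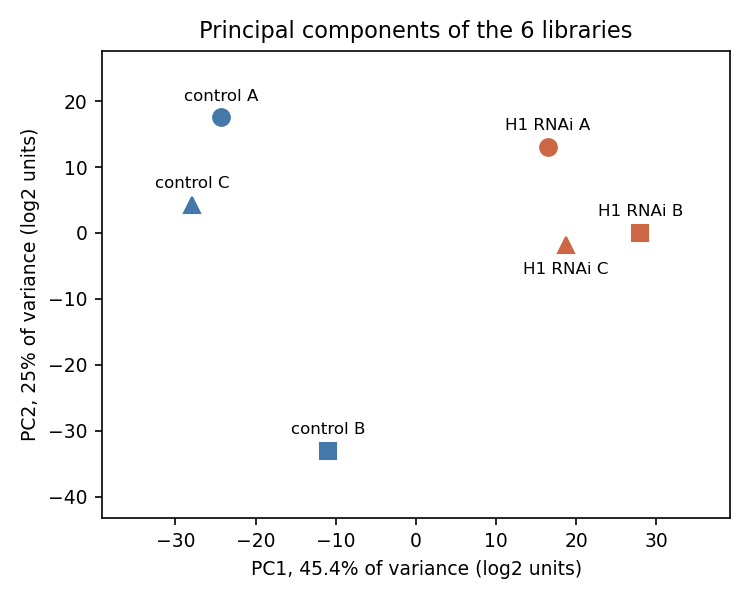
Principal components of log2(TPM + 1) over the 8124 tested genes, 1 point per library, control in blue and H1 RNAi in orange, with circles, squares and triangles for replicates A, B and C. The first component (45.4% of the variance) separates the groups and the second (25%) sets control B apart from the other libraries.

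The RNAi target could not be measured. All 23 His1 gene copies were listed at 0 in all 6 libraries, as were 85 of the 88 core histone copies of the same repeat. Transcripts of these repeat genes normally lack a poly(A) tail and the library kit selects polyadenylated RNA, and how reads matching several copies were counted is not given in the sources used here, so the values do not check the knockdown in either direction. BigH1, the germline H1 variant, was listed at 0.07 TPM or less in each library. The pseudogene His-Psi:CR33867 was listed at 2.46 to 12.9 TPM over the 6 libraries, with overlapping groups. Of the histone genes outside the repeat, His3.3A, which encodes the replacement histone H3.3, rose from 132 ± 24.0 to 283 ± 39.8 TPM (SD, n = 3 per group, log2 fold change 1.10, adjusted p = 0.0314, limma). His3.3B, which encodes the same protein, had a log2 fold change of -0.02, His2Av of -0.11 and His4r of 0.07, with no call. The core histone list thus had 1 of 4 tested members higher and 0 lower, over all genes and adjusted over the list alone. The His3.3A call was lost on leaving out any library except control B, with adjusted p up to 0.14.

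In H1 RNAi a group of genes that were near 0 in control was clearly expressed, while the enteroendocrine peptide genes Tk and NPF were lower, with log2 fold changes of -1.50 and -1.03. The largest rise was that of dysf, a transcription factor known from tracheal fusion cells, listed at 0.02 TPM or less in the control libraries and at 67.2 ± 11.2 TPM in H1 RNAi. The gene with the largest fall was CG45080, which went from 50.4 ± 43.3 to 1.34 ± 2.05 TPM (SD, n = 3 per group). The progenitor genes that were tested did not pass the threshold in either direction, while esg, Dl and hdc had no matching row. Of 8124 genes tested with limma, 230 passed an adjusted p of 0.05, 185 higher and 45 lower in H1 RNAi, and 126 of them had a fold of at least 2 (94 higher, 32 lower). An unadjusted p under 0.05 was found for 1935 genes. The 3 values of the groups did not overlap for 30.8% of tested genes, where chance gives 10% on average, with 1978 of them higher and 524 lower in H1 RNAi. Genes vary together, so the share of a single split can lie far from that average. These counts are as deposited and were not made with other scalings.

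The median log2 fold change of all tested genes was 0.14, so part of the excess of higher calls moved with the scaling. The share of calls that were higher was 80.4% as deposited, 64.7% of 136 calls with TMM scaling (88 higher, 48 lower, median 0.02) and 56.8% of 146 with quantile normalization (83 higher, 63 lower). The total also depended on single libraries. It was 82 without control A, 450 without control B, 34 without control C, 57 without H1 RNAi A, 29 without H1 RNAi B and 37 without H1 RNAi C. Of 46 named genes past the threshold, 16 lost the call with TMM scaling and 13 with quantile normalization.

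**Figure D2:**
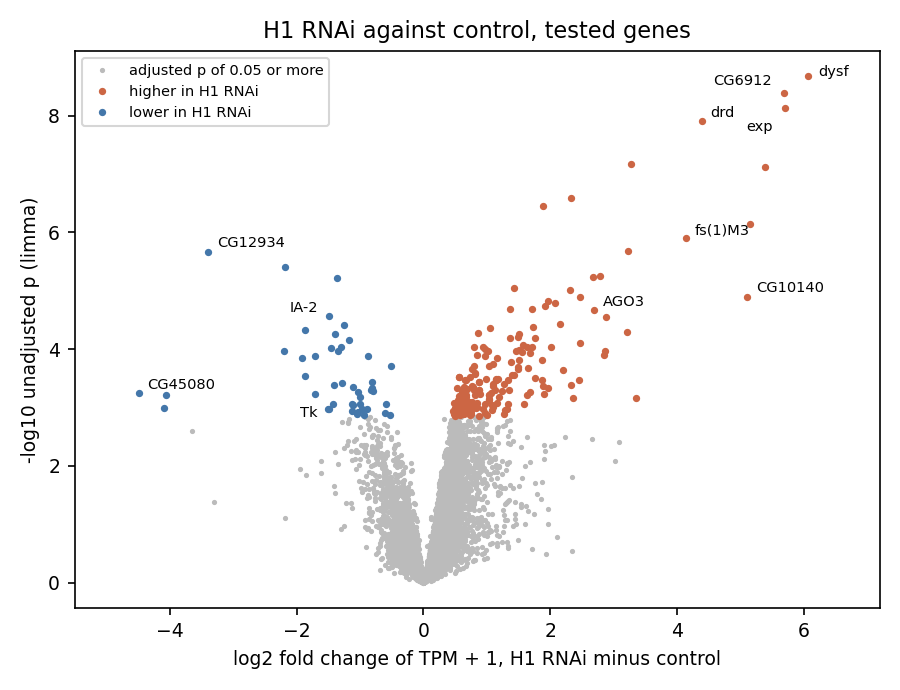
Log2 fold change of TPM + 1 (H1 RNAi minus control, horizontal) against -log10 of the unadjusted limma p (vertical) for the 8124 tested genes, with the 185 higher calls in orange, the 45 lower in blue and other genes in grey. The highest points are dysf, CG6912, exp and drd, with log2 fold changes of 6.07, 5.69, 5.71 and 4.40.

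The 12 largest increases by the fixed rule were dysf, exp, CG6912, asRNA:CR45600, CG14109, CG10140, drd, fs(1)M3, lncRNA:CR43144, FBgn0040813, CG18063 and lncRNA:CR43264. The gene dysf (3R, 26076592 to 26098711 in BDGP6.54) had a log2 fold change of 6.07 ± 0.16 (SE, adjusted p = 1.70e-05). The gene exp (2R, 11939557 to 11967435), whose Smad-like protein is needed for tracheal tubes, was at 0.28 TPM or less in control and 56.1 ± 8.16 TPM in H1 RNAi (log2 fold change 5.71 ± 0.18, adjusted p = 1.99e-05). CG6912 (3R, 15135138 to 15137004) went from 0.793 ± 0.302 to 91.1 ± 10.7 TPM (adjusted p = 1.70e-05), and asRNA:CR45600, which shares 20 bp with it on the same strand, from 0.657 ± 0.474 to 67.6 ± 12.1 TPM. The neighbours CG10140 (3L, 13439317 to 13440470) and CG14109 (3L, 13440910 to 13442420) reached 79.4 ± 40.5 and 40.2 ± 18.4 TPM from 1.27 ± 0.989 and 0.0800 ± 0.0265 TPM. The gene drd, known for a role in gut function and adult survival, was at 21.8 ± 0.944 TPM against 0.0800 ± 0.0346 TPM (log2 fold change 4.40 ± 0.15). The eggshell gene fs(1)M3 was at 21.8 ± 7.32 TPM against 0.237 ± 0.0802 TPM (log2 fold change 4.15 ± 0.27). CG18063 was listed at 0 in all 3 control libraries and at 8.56 ± 2.31 TPM in H1 RNAi. FBgn0040813, which the name tables leave without a symbol, went from 7.09 ± 0.511 to 77.8 ± 13.4 TPM. These calls held with each library left out in turn, except those of lncRNA:CR43144 (adjusted p up to 0.161, kept only without control B, and lost with TMM scaling at 0.0505 and with no filter) and lncRNA:CR43264 (up to 0.0749, lost without control C, H1 RNAi B or H1 RNAi C). The kit is stranded per the labels, but whether counting used the strand is not given in the sources used here, so overlapping neighbours on the other strand may share reads. CG3987, over 164 bp of asRNA:CR45600, was at 118 TPM in control and 169 TPM in H1 RNAi. CG3984, over 1860 bp of asRNA:CR45600, was at 0.897 TPM in control and 0.527 TPM in H1 RNAi. PI31, over 93 bp of exp, was at 76.8 and 91.0 TPM, and CG6067, over 77 bp of fs(1)M3, at 0.297 and 1.23 TPM. Such neighbours of CG18063 and lncRNA:CR43264 had means of 0.17 TPM or less in both groups.

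The 12 largest decreases were CG45080, CG16826, whe, CG12934, Cyp6a17, CG5348, nebu, CR40190, Tk, IA-2, Prx6c and ect. Of these, CG45080, CG16826 and whe varied most between libraries relative to their means, with 50.4 ± 43.3, 40.6 ± 36.9 and 38.0 ± 24.4 TPM in control and 1.34 ± 2.05, 1.22 ± 1.63 and 1.52 ± 2.04 TPM in H1 RNAi. CG12934 (2R, 10648888 to 10649830) went from 71.5 ± 18.5 to 5.86 ± 1.54 TPM, with a log2 fold change of -3.39 ± 0.24 and an adjusted p of 0.00145. Cyp6a17, a cytochrome P450, went from 64.2 ± 15.2 to 13.5 ± 4.42 TPM (log2 fold change -2.19 ± 0.28, adjusted p = 0.0156), and Prx6c, a peroxiredoxin, from 61.0 ± 17.2 to 21.2 ± 6.73 TPM. CG5348 lies on the other strand inside unc-104, which encodes a kinesin motor, and both were lower, with log2 fold changes of -1.91 and -0.93. The calls of CG12934 and IA-2 held with each library left out in turn. Those of CG16826, CR40190, Tk and Prx6c were lost without any library except control B (adjusted p up to 0.172) and, apart from CR40190, with TMM scaling (0.0559 for CG16826, 0.0551 for Tk and 0.0516 for Prx6c), and those of CG45080 and whe without control A, control C, H1 RNAi A or H1 RNAi B (up to 0.14). Quantile normalization also ended the calls of CG16826 and Tk. CG5348 and ect lost theirs without control A, control C, H1 RNAi B or H1 RNAi C (up to 0.0934), nebu without control C, H1 RNAi B or H1 RNAi C (up to 0.0692) and Cyp6a17 without control A, H1 RNAi B or H1 RNAi C (up to 0.0695).

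**Figure D3:**
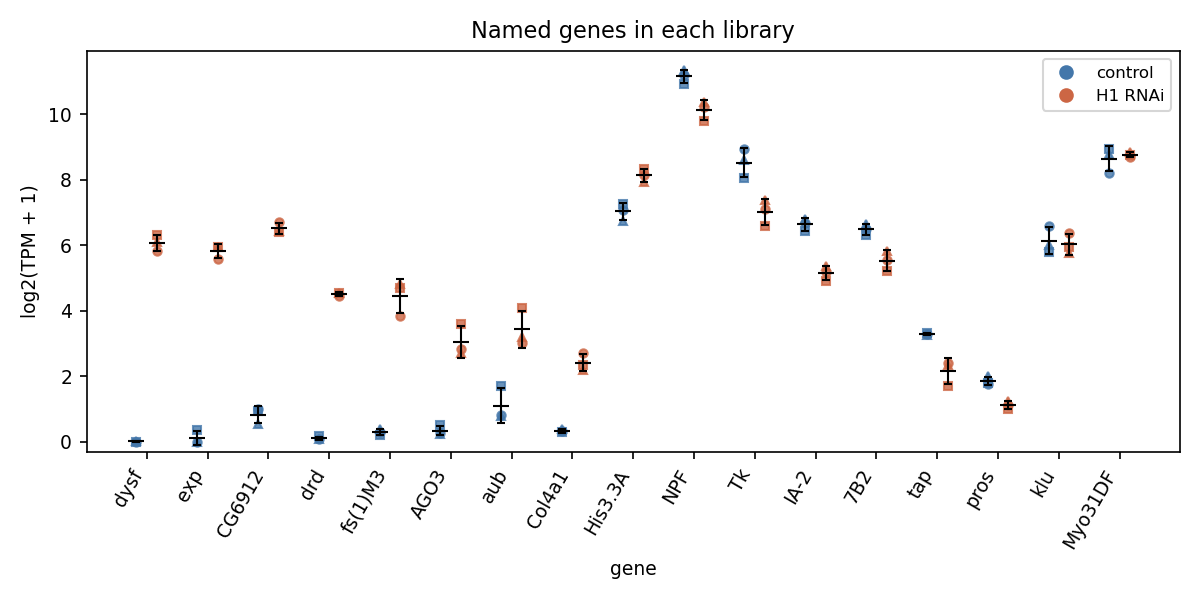
Log2(TPM + 1) of 17 named genes in each library, control in blue and H1 RNAi in orange, with circles, squares and triangles for replicates A, B and C and bars for the mean ± SD of 3 libraries. The genes dysf, exp and drd lie near 0 in every control library, while Tk, NPF, IA-2 and 7B2 lie lower in all 3 H1 RNAi libraries than in any control library.

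Some genes of enteroendocrine cells, the hormone-producing cells of the gut, were lower in H1 RNAi. Of 17 tested hormone and hormone-processing genes, 5 fell, 0 rose and 12 did not pass over all genes, and 7 fell and 2 rose adjusted over the list alone. The list name Nplp2 matched no row by symbol, so that gene is not in these counts. Lists were matched by symbol, so rows without one, such as the strongly raised FBgn0040813, could not be placed on any list. The tachykinin gene Tk (3R, 11994175 to 12005473) fell from 380 ± 113 to 133 ± 35.4 TPM (log2 fold change -1.50 ± 0.28, adjusted p = 0.0452). The neuropeptide F gene NPF (3R, 16609220 to 16611325) fell from 2309 ± 327 to 1139 ± 226 TPM (-1.03 ± 0.17, adjusted p = 0.0345). IA-2 (2L, 1008378 to 1048053), a protein of dense-core vesicles, fell from 99.3 ± 13.1 to 34.8 ± 5.39 TPM (-1.49 ± 0.15, adjusted p = 0.00805), and 7B2, a chaperone of prohormone convertase, from 89.6 ± 10.8 to 45.8 ± 10.2 TPM. The fifth was Pal2, a peptide amidation enzyme named after its values were seen, with a log2 fold change of -1.05. Members that rose on the list-alone adjustment were Mip (log2 fold change 1.20) and CCHa2 (1.09), neither past the threshold over all genes. AstC was at 24.3 ± 11.2 TPM in control and 14.5 ± 4.16 TPM in H1 RNAi (adjusted p = 0.382). As a set the list was lower than other genes by limma's camera test with a preset correlation (adjusted p = 2.25e-06), but not with an estimated one (adjusted p = 0.234 with an estimated correlation). The number that fell was 1 without control A, control C or any H1 RNAi library, 6 without control B, 1 with TMM scaling and 2 with quantile normalization. The list median, -0.39, was -0.70 with a filter at 5 TPM and -0.59 without control A. The calls of Tk, NPF and 7B2 were lost without any library other than control B (adjusted p up to 0.172, 0.127 and 0.16), and also with TMM scaling (0.0551, 0.0530 and 0.0627). Tk overlaps Ect3 on the other strand, at 3.80 TPM in control and 4.11 TPM in H1 RNAi.

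Of 9 tested enteroendocrine fate regulators, 2 fell and 0 rose over all genes, and 5 fell adjusted over the list alone. The transcription factor genes mirr (5.23 ± 0.926 to 2.09 ± 0.254 TPM, adjusted p = 0.0418) and tap (8.80 ± 0.295 to 3.57 ± 1.12 TPM, adjusted p = 0.0463) passed. The fate factor pros was at 2.62 ± 0.334 and 1.18 ± 0.175 TPM (log2 fold change -0.73, adjusted p = 0.0787), and Rab3, a vesicle GTPase, had a log2 fold change of -0.74 (adjusted p = 0.0598). The list was lower as a set (adjusted p = 2.84e-06, camera; adjusted p = 0.0870 with an estimated correlation). Of 13 tested neuronal genes, 1 rose, 1 fell and 11 did not pass, and adjusted over the list alone 9 fell and 1 rose. The call up was unc-13, a synaptic vesicle priming factor (log2 fold change 0.99, adjusted p = 0.0289), and the call down was unc-104 (-0.93, adjusted p = 0.0490), while the synaptic genes nSyb (-0.90) and Nrx-1 (-0.68) had adjusted p of 0.0779 and 0.0789. The neuronal set was lower than other genes (adjusted p = 1.36e-06, camera; adjusted p = 0.0870 with an estimated correlation). The call of tap was lost without each library in turn (adjusted p up to 0.145), and those of mirr (up to 0.183) and unc-104 (up to 0.19) without any library except control B and with quantile normalization, mirr also with TMM scaling (0.0516). The unc-13 call was lost without control C or any H1 RNAi library (up to 0.137). The median log2 fold changes, -0.73 for fate regulators and -0.68 for neuronal genes, were -0.05 and 0.11 with a filter at 5 TPM, which left 4 and 5 genes, and -0.04 and -0.01 with no filter, over 15 and 30 genes.

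No tested member of the progenitor list passed in either direction. Of 17 tested ISC and EB genes, 1 had an unadjusted p under 0.05 (limma), and the list median log2 fold change was 0.02. The neuroblast gene mira was at 108 ± 16.1 TPM in control and 167 ± 35.4 TPM in H1 RNAi (adjusted p = 0.118), and klu, a factor of enteroblasts, at 71.9 ± 21.8 and 65.7 ± 15.3 TPM (log2 fold change -0.11, adjusted p = 0.823). The symbols esg, Dl and hdc matched no row of the values used and are not analysed here. Of 6 tested Notch target genes 0 passed (1 at an unadjusted p under 0.05). The highest of those named, E(spl)mbeta-HLH, was at 964 ± 72.9 TPM in control and 926 ± 90.3 TPM in H1 RNAi, and E(spl)mgamma-HLH at 3.49 ± 1.65 and 8.02 ± 1.97 TPM (adjusted p = 0.117). Neither set passed the camera test (adjusted p = 0.166 and 0.359), but without control B the progenitor set was lower than other genes (adjusted p = 0.00918) with a median of -0.06.

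Genes of mature enterocytes, the absorptive cells, gave few calls. Of 41 tested digestive enzyme genes 1 rose and 40 did not pass over all genes, and 3 rose adjusted over the list alone. The maltase gene Mal-B2 rose from 1.13 ± 0.501 to 4.13 ± 1.04 TPM (adjusted p = 0.0478), while mag, a lipase, was at 4.30 ± 1.61 and 27.1 ± 15.8 TPM (adjusted p = 0.0700) and the protease gene Jon65Aii at 3.81 ± 2.84 and 30.9 ± 18.9 TPM (adjusted p = 0.0716). The list median log2 fold change was 0.69, but the set did not pass (camera adjusted p = 0.349). It passed as higher without control B (0.0176, 4 members higher, median 1.12) and without H1 RNAi A (0.0405), while without control A the median was 0.23 and the test direction was down (0.702). Of 17 tested enterocyte identity and junction genes 0 passed and 2 had an unadjusted p under 0.05. Myo31DF, a brush border myosin, was at 410 ± 102 and 437 ± 25.9 TPM (adjusted p = 0.748), nub at 2.12 ± 0.939 and 1.56 ± 0.609 TPM, and Hnf4 had a log2 fold change of -0.26 (adjusted p = 0.178). The identity set did not pass (camera adjusted p = 0.166) but was lower without control A (0.0380). The Mal-B2 call was lost without any library except control B (adjusted p up to 0.205) and with TMM scaling (0.0716).

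Among 17 tested germline genes, 3 rose and 0 fell over all genes, and 5 rose adjusted over the list alone. The Piwi-family genes AGO3 (0.273 ± 0.127 to 7.55 ± 3.07 TPM, log2 fold change 2.69 ± 0.27, adjusted p = 0.00677) and aub (1.25 ± 0.892 to 10.4 ± 4.85 TPM, 2.33 ± 0.37, adjusted p = 0.0320) and the piRNA cluster factor del (17.5 ± 4.76 to 38.1 ± 5.90 TPM, adjusted p = 0.0445) passed, and tej did not (log2 fold change 0.96, adjusted p = 0.0824). The set did not pass the camera test (adjusted p = 0.166). The AGO3 call held with each library left out in turn, that of aub was lost without any library except control B (adjusted p up to 0.121), and that of del without control C or any H1 RNAi library (up to 0.17) and with TMM scaling (0.0623). Of 24 heterochromatin factors 1 rose, HP1c, a heterochromatin protein 1 paralog (13.9 ± 1.25 to 20.9 ± 1.06 TPM, adjusted p = 0.0468), over all genes and adjusted over the list alone. That call was lost without each library in turn (adjusted p up to 0.213) and with TMM scaling (0.0990). Of 21 Polycomb group genes 0 passed (3 at an unadjusted p under 0.05, limma), with log2 fold changes of 0.67 for esc and 0.53 for escl, and of 5 tested Hox and segmentation genes 0 passed (0 at an unadjusted p under 0.05). Set tests for these lists gave adjusted p of 0.166 for heterochromatin, 0.855 for Polycomb and 0.337 for Hox and segmentation genes. No row of the table matched a name in the transposable element list.

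Of 51 tested cell cycle genes 2 rose, over all genes and adjusted over the list alone, and 49 did not pass. They were Cap-G, a condensin subunit (11.2 ± 1.11 to 17.8 ± 0.560 TPM, adjusted p = 0.0374), and thr, which acts with separase (1.28 ± 0.295 to 3.63 ± 0.195 TPM, adjusted p = 0.0383). PCNA, the replication clamp, had a log2 fold change of 1.32 (adjusted p = 0.0988). The set was higher than other genes (camera adjusted p = 0.0469; adjusted p = 0.727 with an estimated correlation), and that call was lost without control B (0.0528), control C (0.350), H1 RNAi A (0.108) or H1 RNAi B (0.135) and with a pseudocount of 0.1 (0.0519). The list median, 0.37, was 0.17 with quantile normalization, 0.22 with a pseudocount of 5 and 0.15 without control C. Of 28 tested DNA damage and apoptosis genes 2 rose by both adjustments, among them the effector caspase gene Dcp-1 (51.6 ± 4.87 to 99.9 ± 8.29 TPM, adjusted p = 0.0154), which overlaps pita on the other strand over 2235 bp. The calls of Cap-G and thr were lost without any library except control B (adjusted p up to 0.181 and 0.175), and that of Dcp-1 without control C or any H1 RNAi library (up to 0.0791). With TMM scaling Cap-G and Dcp-1 had adjusted p of 0.0516, and 0 damage genes passed. Without control B 8 damage genes and 5 cell cycle genes rose, and the damage set passed as higher (0.00651, against 0.166 with all libraries). Damage genes that rose numbered 1 without control A and 0 without control C or any H1 RNAi library.

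Stress and signalling lists gave few calls. Of 12 tested antimicrobial and immune genes 1 rose over all genes and 4 adjusted over the list alone. PGRP-SC2, a peptidoglycan amidase, rose from 2.23 ± 0.965 to 16.5 ± 9.19 TPM (adjusted p = 0.0374), while the peptide gene AttD was at 4.24 ± 2.21 and 19.4 ± 9.91 TPM (adjusted p = 0.0779). Of 20 heat shock genes 0 passed and 3 had an unadjusted p under 0.05 (limma). Hsp70Ba, at 51.5 ± 21.7 and 25.5 ± 1.76 TPM, shares near-identical sequence with other Hsp70 copies, so its value is uncertain. The heat shock set was lower than other genes (camera adjusted p = 4.24e-05; adjusted p = 0.699 with an estimated correlation), with a median of -0.27 (-0.10 without control A and -0.11 without H1 RNAi C). Over all genes 0 passed of 20 JNK and stress genes (3 at an unadjusted p under 0.05, 1 higher adjusted over the list alone, Tsp42Ej), 10 JAK/STAT genes (2) and 22 EGFR and Wnt genes (1). The set tests of these lists, of damage genes and of immune genes gave adjusted p of 0.166 except JAK/STAT (0.999). Without control B 3 immune genes rose. PGRP-SC2 lost its call without any library except control B (adjusted p up to 0.127) and with TMM scaling (0.0631).

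Nuclear-encoded oxidative phosphorylation genes were higher than other genes as a set, with a median log2 fold change of 0.28 against 0.14 for all genes (0.16 against 0.02 with TMM scaling, and 0.17 without control C), although 0 of 66 members passed and 11 had an unadjusted p under 0.05 (camera adjusted p = 0.00690; adjusted p = 0.727 with an estimated correlation). That call was lost without control B (0.0941), control C (0.143) or H1 RNAi B (0.135). Of 83 ribosomal protein genes 1 fell, RpL23A (6696 ± 460 to 4674 ± 244 TPM, adjusted p = 0.0220), by both adjustments, and the set was lower than other genes (camera adjusted p = 2.84e-06; adjusted p = 0.699 with an estimated correlation) with a median of -0.05 as deposited, -0.17 with TMM scaling and 0.01 with quantile normalization. With 1 library left out the ribosomal median ran from -0.10 (without control B) to -0.02 (without control C). Of 69 detoxification genes 1 fell, Cyp6a17, by both adjustments, and the set was lower (camera adjusted p = 0.0238; adjusted p = 0.704 with an estimated correlation), a call lost with TMM scaling (0.128) and without control B (0.761), control C (0.0739) or H1 RNAi A (0.487). Without control B 7 detoxification genes rose. Of 19 mitochondrially encoded genes 1 rose by both adjustments, mt:ATPase8 (1.37 ± 0.304 to 3.87 ± 0.430 TPM, adjusted p = 0.0395), which shares 7 bp with mt:ATPase6, and of 15 glycolysis genes 0 passed (3 at an unadjusted p under 0.05). Their set tests gave adjusted p of 0.166 and 0.207. The calls of RpL23A and mt:ATPase8 were lost without any library except control B, with adjusted p up to 0.106 and 0.14, and with TMM scaling (0.0516 and 0.0656).

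Of the 28 lists with a set test, 8 passed with the preset correlation and 0 with an estimated correlation (3 at an unadjusted p under 0.05). None of the camera calls above thus holds under both correlations. By fry's directional test the hormone (adjusted p = 0.0336), fate regulator (0.00516) and neuronal (0.00414) lists passed as lower. The tracheal (0.000161) and immune (0.0250) lists passed as higher. The tracheal list, with 5 tested members of which dysf and exp were called, had a mean log2 fold change of 2.21 but a median of 0.13. The heat shock, ribosomal, oxidative phosphorylation, cell cycle and detoxification lists did not pass by fry. Other splits of the same 6 libraries into 3 and 3 gave 2 to 13 lists by the preset test. Camera compares a list with the other genes, whose median log2 fold change was 0.14, so a list with a positive median can test as lower. Median and mean were positive and the test negative for the progenitor, JAK/STAT, EGFR and Wnt, hemocyte, fat body and ovary, sex-linked, glycolysis and detoxification lists. The mean was positive, with a negative median and test, for the Notch target, enterocyte identity, Hox and JNK lists, and the mean was negative with a positive median for mitochondrially encoded genes. With TMM scaling the medians of the core histone, progenitor, Polycomb, JAK/STAT, EGFR and Wnt, hemocyte, fat body and ovary, mitochondrially encoded, glycolysis and detoxification lists were negative, and all of these but the core histone median were negative with quantile normalization, as were the tracheal and sex-linked medians.

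**Figure D4:**
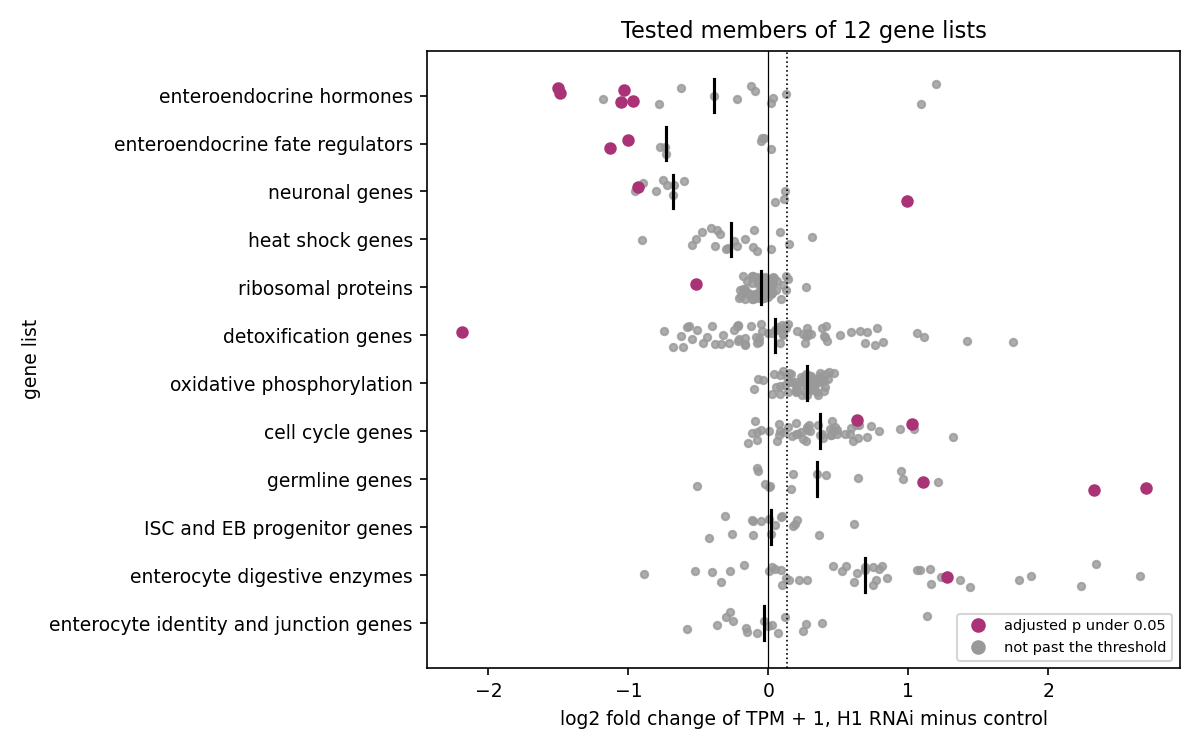
Log2 fold change of TPM + 1 (H1 RNAi minus control) of the tested members of 12 gene lists, 1 point per gene, with genes past the threshold in purple, black bars for list medians and a dotted line at the median of all genes, 0.14. The median lies at -0.39 for enteroendocrine hormones and -0.73 for enteroendocrine fate regulators (-0.70 and -0.05 with a filter at 5 TPM), 0.69 for digestive enzymes and 0.02 for progenitor genes (-0.10 with TMM scaling).

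Markers of cell types that a dissected gut can also carry were mostly low. Of 7 tested visceral muscle markers 1 fell by both adjustments, Msp300, a nesprin (77.5 ± 7.37 to 50.9 ± 1.31 TPM, adjusted p = 0.0418). Of 9 tested hemocyte markers 2 rose by both adjustments, the neighbouring collagen IV genes Col4a1 (0.260 ± 0.0458 to 4.38 ± 0.998 TPM, adjusted p = 0.00590) and vkg (0.150 ± 0.0693 to 2.93 ± 0.767 TPM, adjusted p = 0.0132), and the laminin gene LanB1 fell adjusted over the list alone only (log2 fold change -0.75). Of 5 tested tracheal markers 2 rose by both adjustments, dysf and exp, and mspo fell adjusted over the list alone only (-0.73). Of 5 tested fat body and ovary markers 0 passed over all genes (2 at an unadjusted p under 0.05) and apolpp fell adjusted over the list alone (2.01 ± 0.0954 and 0.837 ± 0.123 TPM), and of 5 tested sex-linked indicator genes 0 passed (1 at an unadjusted p under 0.05). Set tests for these lists gave adjusted p of 0.166 for muscle, 0.868 for hemocytes, 0.166 for trachea, 0.269 for fat body and ovary and 0.855 for sex-linked genes. The yolk protein genes were high in control B alone, at 43.5 TPM for Yp1, 22.7 TPM for Yp2 and 19.4 TPM for Yp3, against 1.22 TPM or less in every other library, and lncRNA:roX1, a male-specific RNA, was at 0.06 TPM or less in all 6. The Msp300 call was lost without any library except control B (adjusted p up to 0.199), and that of vkg without control C, H1 RNAi B or H1 RNAi C (up to 0.0684).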

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

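The comparisons with other splits of the libraries were tests chosen only after the result was seen, and the other alternatives were planned. All 230 calls kept their sign with TMM scaling and quantile normalization, while the other alternatives cannot turn a sign because the groups of these genes do not overlap. The counts stayed within 1.5 times with a pseudocount of 0.1 and with ordinary moderation. Calls numbered 90 without the filter (75 higher, 15 lower, 77 with a fold of at least 2), where 13713 genes shared the adjustment and 84 calls were shared. They numbered 136 with TMM scaling (88 higher, 120 shared) and 146 with quantile normalization (83 higher, 119 shared), which move the median of all genes from 0.14 to 0.02 and -0.01. Array weights gave 547 calls (446 higher, 101 lower, 206 with a fold of at least 2), and a pseudocount of 5 left 57 with that fold because it shrinks changes of low genes. Leaving out 1 library gave 29 calls (without H1 RNAi B) to 450 (without control B), with 24 to 389 higher, 5 to 61 lower and 29 to 245 with a fold of at least 2. Apart from what fewer libraries, more tested genes or the pseudocount do by construction, the cause was not tested. With the replicate letter as a block there were 142 calls (107 higher), 110 of them shared. The letters were not treated as pairing, because the labels do not say that they mark shared days or flies. The correlations of deviations within letters were 0.40, 0.14 and 0.093. Between letters they ran from -0.28 to 0.17, with only that of control B and H1 RNAi C positive. These values do not settle whether the letters pair the libraries.

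Of 28 gene lists with a set test, 8 passed with the preset correlation, 0 with an estimated correlation (3 at an unadjusted p under 0.05), 5 with fry's directional test and 14 with its mixed test, and 5 (without control C) to 9 (without control A) with 1 library left out. The cause was not tested. Of 46 named genes past the threshold, 14 kept the call under every alternative that tested them. The His1 level was 0 in every setting. Count-based tests were not run because the table holds TPM, and depth is unknown, so counting error cannot be told from other spread.

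The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 230 calls, 185 higher, 45 lower and 126 with a fold of at least 2, and the highest other split gave 0 of each with limma (57 to 842 genes at an unadjusted p under 0.05, against 1935), so 1 of the 10 splits was as large for each count. For gene lists 5 of the 10 splits gave at least the real 8, with 13 the highest.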

Other observations

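The tests of tracheal cells, of a broad rise of silent genes and of the summed follicle cell markers were written before their results, and the other tests below were chosen only after the result was seen. The genes in this paragraph were chosen after their values were seen. The gene grk, which encodes a TGF-alpha-like ligand of the oocyte, went from 0.173 ± 0.107 to 3.58 ± 0.471 TPM (SD of 3 libraries, log2 fold change 1.96, adjusted p = 0.00576, limma). The embryonic patterning gene trk had a log2 fold change of 1.43 (adjusted p = 0.0276) and Marf1 of 1.64 (adjusted p = 0.0355). Among other germline genes vas was at 0.13 TPM or less and osk at 0.41 TPM or less in every library, while tud was at 53.2 to 68.7 TPM with a log2 fold change of -0.08 (adjusted p = 0.738). The metallothionein gene MtnA went from 28.5 ± 6.93 to 81.9 ± 11.6 TPM (log2 fold change 1.51, adjusted p = 0.0156), and MtnE and MtnD had log2 fold changes of 1.04 and 0.97 (adjusted p = 0.0220 and 0.0418), while MtnC did not pass (1.14, adjusted p = 0.104).

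Other genes chosen after their values were seen include the receptor tyrosine kinase gene Ret, which went from 3.78 ± 0.752 to 32.6 ± 8.87 TPM (log2 fold change 2.79, adjusted p = 0.00306, limma). The histone chaperone gene asf1 had a log2 fold change of 0.77 (adjusted p = 0.0418). The Runx transcription factor gene lz went the other way, from 3.64 ± 0.204 TPM to 0.05 TPM or less in each H1 RNAi library (log2 fold change -2.19, adjusted p = 0.00248).

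Of 17 enteroendocrine hormone genes 5 fell in H1 RNAi, among them Tk (log2 fold change -1.50) and NPF (-1.03), whose calls were lost with TMM scaling (adjusted p = 0.0551 and 0.0530, limma), and the set had an adjusted p = 0.234 with an estimated correlation. A loss of enteroendocrine cells of every class alike would give all peptide genes 1 common change. Only peptide genes with a mean of at least 5 TPM over the 6 libraries entered this test. The 95% intervals of 57.1% of these (4 of 7) exclude the common -0.47, with Mip at 0.38 to 2.02 and Tk at -2.16 to -0.84. That common value was estimated from the same 7 genes, but the intervals of NPF (-1.43 to -0.62) and ITP (-0.27 to 0.52) share no value either. List members that encode no peptide, such as IA-2 and 7B2, were not in this test, and an unequal loss of such cells stays open. The list median was -0.513 with TMM scaling and -0.392 as deposited, so its sign did not need the deposited scaling. But TMM scaling moved the median of all genes from 0.14 to 0.02, so a negative list median had to become more negative. With it 1 member fell, so the test cannot decide whether scaling contributed to the calls. Lower expression per cell stays open, with 12 of 17 members lower, because RNA from pooled cells counts no cells. A change in some classes of enteroendocrine cells may give the same values. The sort for esg-driven GFP is meant to leave such cells out, but control libraries held NPF at 2309 ± 327 TPM and Tk at 380 ± 113 TPM. Enteroendocrine transcripts were therefore present in the sorted samples, and their source was not tested.

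The genes near 0 (under 0.5 TPM) in every control library and at 1 TPM or more in every H1 RNAi library numbered 29, against 4 the other way (87.9% on, 95% exact interval 71.8% to 96.6%). The interval treats genes as independent and does not measure the spread between libraries. Tracheal cells that carry 9 other tracheal markers are argued against. These markers summed to at most 31.7% of dysf in any H1 RNAi library, at 9.45 to 17.7 TPM against 11.3 to 21.3 TPM in control. The sum left out the list members exp, bnl and mspo. Of these exp is itself a gene of the pattern, at 46.7 to 61.0 TPM in H1 RNAi. Cells that express dysf and exp without those 9 markers are not addressed. A difference in genetic background between the lines crossed could not be excluded. Of the 29, 6 lie within 100 kb of another, the collagen genes vkg and Col4a1 among them. Random silent genes gave a median of 2 and a 95th percentile of 5 (permutation p = 0.049, 10000 draws). Of 4857 genes under 0.5 TPM, 44.4% had a higher mean in H1 RNAi, which by the rule written beforehand counts against a broad rise, but the share was 55.5% without control B, 45.2% without control A and 41.5% without control C. The need for the same answer without each control was added after that result was seen, so a broad rise stays open, as does a direct effect of the H1 knockdown, which was not tested.

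Yolk protein transcripts stood out in control B alone, at 43.5 TPM for Yp1, beside TotC (27.1 TPM), CG4716 (21.7 TPM) and Tdh (19.4 TPM), which were chosen after their values were seen and are 3 of 6 genes at 10 TPM or more and 10 times every other library there (H1 RNAi C had 6 such genes too, and H1 RNAi B 3). Fat body cells stay open as a source. The sum of 8 other fat body markers was 7.21 TPM in control B, 1.75 times the next control library, and up to 6.12 TPM in H1 RNAi. That sum cannot decide, because its members are low and went different ways. Lsp1gamma was at 2.78 TPM in control B but up to 4.31 TPM in H1 RNAi, and apolpp at 1.92 to 2.11 TPM in the controls. Apoltp was at 0.92 TPM in control B and 0.11 TPM or less elsewhere. Whether adult fat body expresses each marker was not tested. Follicle cells that make vitelline membrane or chorion transcripts are argued against, because the highest of 6 such transcripts in control B was 2.01% of the lowest yolk gene, and they summed to 0.55 TPM there and up to 0.56 TPM in H1 RNAi. Other follicle cells stay open, with the sum of these transcripts and Fcp3C at 4.12 TPM in control B, against 2.53 TPM in the next control library and up to 3.89 TPM in H1 RNAi, most of it Fcp3C. The GFP sort is meant to remove either cell type, and the design gives no biological explanation to test for 1 library.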
